A study of Homo sapiens with 18 samples.

How the data were processed

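RNA immunoprecipitation sequencing (RIP-seq) recovers RNA together with a tagged protein and compares it with the RNA of the starting lysate, the input. HEK293T cells, a human embryonic kidney line that transfects readily, received a Flag vector (control), Flag-SBP2, or Flag-SBP2 followed by 100 nM sodium selenite 4 h after transfection. Lysates were collected at 48 h, 4 mg of protein was incubated with anti-Flag beads for 5 h, and the beads were washed in 300 and then 500 mM KCl, per the labels' protocols. The input was 1 part in 5 of each sample, taken before the incubation. The 3 treatments, each with input and RIP libraries and 3 biological replicates per the series design, gave 6 groups and 18 libraries. Each sample was placed in its group, with its replicate number, by its title. The labels do not state whether replicates were transfected on separate days.

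The authors deposited whole-number counts per gene for the 18 libraries. Reads were trimmed with Trim Galore 0.6.6, aligned with STAR 2.7.6a and counted with featureCounts 2.0.1 against GRCh38 (hg38), per the submitters' processing notes. The gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Counts of overlapping genes, antisense partners, paralogs and pseudogenes may therefore hold reads of one another. The deposited counts named genes by Ensembl ID only. The files do not pair these IDs with symbols: 0 of the 59792 genes in the reference gene table carried an Ensembl ID, so 0 IDs matched. IDs are given as deposited, with at most 2 that rose and 2 that fell per comparison, and no gene coordinates are given. The 25 gene lists fixed beforehand, SECISBP2 (the gene that encodes SBP2), the selenoprotein genes and the mitochondrial genes were therefore not analysed here by name. A search for SECIS motifs was not run, since no genome sequence was used.

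Library totals ran from 15.2 to 29.9 M counts (M, counts divided by 1e+06), and 35033 of 58676 IDs had at least 1 count. The filterByExpr function of edgeR 4.0.16, with its minimum count of 10 and minimum total of 15, kept 17678 IDs over 18 libraries and 16616 over the 9 inputs. The kept IDs held at least 99.9% of the counts of each library. Replicate pairs differed by 4.76 to 27.3 times the sampling noise (chi-square per degree of freedom), so no library was counted as a duplicate of another.

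Counts were scaled by TMM factors and tested with edgeR's two-sided quasi-likelihood test in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. RIP comparisons used 1 group-means model over 18 libraries, which shares the spread between groups, and input comparisons used the 9 inputs. Enrichment over control was the RIP-to-input difference with SBP2 minus that of the control, on the log2 scale. The selenite effect was the same difference between both SBP2 treatments. Standard errors of log2 changes were derived from the test statistic. Ratios of single lysates were differences of log2 CPM (counts scaled to 1e+06 per library) with a prior count of 2.

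Named IDs followed a rule set before the data were examined: the largest changes in each direction with a passing adjusted p, a log2 change of 1 or more, a mean log2 CPM of 1 or more and replicates that did not overlap between groups. The fold limit was dropped where fewer than 10 IDs reached it, and the first 2 of each direction are given. The parts of the rule that name SECISBP2, selenoproteins and list members were not used. A strongly enriched set, with a log2 enrichment of 3 or more both with and without selenite and a mean log2 CPM of 1 or more, was chosen after counts at limits from 1 to 5 had been seen. Tests of this set used camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, all on voom values with limma 3.58.1. Their p-values were adjusted over 4 comparisons.

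The overlap of comparisons that share control libraries was set against 20 simulated data sets without effects and against the overlap of independent lists. On simulated data with 200 changed IDs, edgeR recovered 64% of changes of log2 1 and 84% of log2 2 for the SBP2 enrichment over 17531 IDs. For the selenite effect it recovered 54% and 79% over 17515 IDs, and for SBP2 inputs with against without selenite 77% and 96% over 16630 IDs.

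Pairing by replicate number was checked by the correlation of deviations from group means. An input and the RIP of the same treatment and number were taken as 1 lysate, since the protocol draws the input from the sample before precipitation, although their correlations were only 0.0012 to 0.19. Inputs with selenite correlated with same-numbered control inputs at 0.17 to 0.41 and with same-numbered SBP2 inputs at 0.15 to 0.26. Every such pair was above 0.1, so the numbers were taken to pair these inputs. Same-numbered SBP2 and control inputs correlated at 0.089 to 0.28, the lowest under this limit, against at most 0.043 with other numbers. All 9 inputs correlated best with an input of their own number, so the limit alone does not speak against pairing SBP2 with control inputs. The tests kept the model without a block that was set beforehand, and counts with the number as a block are given beside them. Alternatives covered the scaling, the test (DESeq2 1.42.0 and limma voom with quality weights), the low-count filter, the fold limit, replicate blocks, the libraries fitted and libraries left out. DESeq2 gave no adjusted p to 1371 IDs in the enrichment with selenite and to 323 in each comparison with control inputs, and these were not counted as passing. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.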

Results

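The data comprised 18 RIP-seq libraries from cells given as HEK293T, although the growth protocol names HEK293. Input libraries held 18.2 ± 2.78 M counts in the control, 18.3 ± 3.44 M with SBP2 and 18.1 ± 1.32 M with SBP2 and selenite (SD, n = 3). RIP libraries held 27.5 ± 2.65, 26.8 ± 1.64 and 23.2 ± 3.1 M counts (SD, n = 3). Between 22712 and 24965 IDs were detected per library. The first principal component carried 61.9% of the variance and separated inputs from RIP libraries. The second carried 17.1% and separated control RIP, at 55.7 to 58.2, from SBP2 RIP, at -41.0 to -37.8 without and -31.5 to -30.1 with selenite.

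The control precipitation measured which RNAs anti-Flag beads recovered without a Flag-tagged protein of interest. ENSG00000187240 rose from 35.2 ± 4.86 CPM in input to 261 ± 18 CPM in control RIP, and ENSG00000078246 from 31.3 ± 4.36 to 225 ± 29.7 CPM (SD, n = 3). Their log2 changes were 2.89 (SE 0.119, edgeR adjusted p = 1.63e-16) and 2.84 (SE 0.106, edgeR adjusted p = 3.16e-17). ENSG00000274012 fell from 53.3 ± 25.6 to 0.745 ± 0.489 CPM (log2 -6.11, SE 0.393, edgeR adjusted p = 5.54e-13). ENSG00000230777 fell from 4.47 ± 0.708 to 0.156 ± 0.0777 CPM (log2 -4.77, SE 0.304, edgeR adjusted p = 4.69e-13). Of 17678 IDs, 5571 were higher and 7039 lower in control RIP than in input, with 2299 and 3911 at 2-fold or more. The share higher was 44.2%, and library size alone turned the balance, to 6600 higher and 5952 lower (52.6%). No low-count filter turned it too (6580 and 6099), while DESeq2 size factors gave 6238 and 6333.

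Flag-SBP2 RIP against its own input gave the RNAs recovered in that precipitation, with the background of the beads included. SBP2 is the protein that binds SECIS elements in selenoprotein mRNAs and takes part in selenocysteine insertion. ENSG00000183291 rose from 269 ± 45.9 CPM in input to 2840 ± 96.9 CPM in RIP (log2 3.40, SE 0.159, edgeR adjusted p = 3.21e-15). ENSG00000211450 rose from 53.3 ± 8.58 to 561 ± 67.8 CPM (log2 3.40, SE 0.127, edgeR adjusted p = 7.41e-17). In control lysates both were lower in RIP than in input, at log2 ratios of -0.94 ± 0.42 and -1.01 ± 0.25 (SD, n = 3). ENSG00000274012 and ENSG00000266402 were lower, at log2 changes of -4.86 and -4.19 (edgeR adjusted p = 1.04e-10 and 7.35e-12). Both were also lower in control RIP than in control input, at -6.11 and -4.06 (edgeR adjusted p = 5.54e-13 and 1.46e-11). Neither passed in the SBP2 enrichment over control (edgeR adjusted p = 0.137 and 0.865), so these falls were not particular to SBP2. In all, 5362 IDs were higher and 5606 lower, with 1519 and 2605 at 2-fold or more (48.9% higher, against 51.3% with library size alone).

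With selenite, ENSG00000183291 and ENSG00000211450 were again the IDs named first. The first rose from 221 ± 33.4 to 2580 ± 327 CPM (log2 3.54, SE 0.16, edgeR adjusted p = 2.06e-15), and the other from 75.7 ± 2.07 to 804 ± 78.7 CPM (log2 3.41, SE 0.126, edgeR adjusted p = 6.04e-17). ENSG00000274012 and ENSG00000230777 were lower, at log2 changes of -4.77 and -4.60 (edgeR adjusted p = 8.84e-11 and 4.74e-12). In control RIP they lay at -6.11 and -4.77 against input, and neither passed in the enrichment over control with selenite (edgeR adjusted p = 0.109 and 0.861). Here 5422 IDs were higher and 5581 lower, with 1491 and 2618 at 2-fold or more (49.3% higher, against 52.8% with library size alone).

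The SBP2 enrichment over control asked which RNAs were recovered with SBP2 beyond the background of the Flag precipitation, which bears on the search for RNAs with functional SECIS elements. ENSG00000198832 had a log2 RIP-to-input ratio of -3.35 ± 0.053 in control lysates and 2.91 ± 0.24 in SBP2 lysates (SD, n = 3). Its enrichment of 6.29 on the log2 scale (SE 0.143, 78.1-fold, edgeR adjusted p = 2.09e-20) ranked first. ENSG00000167468 went from -2.46 ± 0.14 to 3.39 ± 0.21 (SD, n = 3), an enrichment of 5.85 (SE 0.139, 57.6-fold, edgeR adjusted p = 2.97e-20). In SBP2 RIP its level reached 7050 ± 492 CPM, against 153 ± 7.98 CPM in control RIP. ENSG00000271971 fell by 2.14 (SE 0.308, edgeR adjusted p = 4.12e-06), with a ratio of 2.13 ± 0.36 in control and 0.037 ± 0.059 in SBP2 lysates. ENSG00000259820 also fell by 2.14 (SE 0.419, edgeR adjusted p = 0.000203), from 0.81 ± 0.42 to -1.25 ± 0.31. Both were rare, with 0.929 ± 0.262 and 2.05 ± 0.755 CPM in control input. The input level of ENSG00000271971 was 1.96 ± 0.191 CPM with SBP2, and RIP against RIP without inputs gave -1.08 for this ID (edgeR adjusted p = 1.55e-05). For ENSG00000259820 it gave -1.52 (edgeR adjusted p = 6.62e-05).

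In total 3844 IDs were enriched and 3201 depleted relative to the control, with 1691 and 592 at 2-fold or more. Of the enriched IDs, 1763 (45.9%) were also higher in SBP2 RIP than in input, while 1150 remained lower than input. Scaling by library size alone turned the balance, to 3007 enriched and 4368 depleted IDs (40.8% higher, against 54.6%). So did DESeq2 size factors (3310 and 3889), the DESeq2 test (3316 and 3900) and no low-count filter (2917 and 4159). Upper-quartile factors (3645 and 3423) and limma voom (4214 and 3786) did not. Library size alone moved the median of all IDs from 0.022 to -0.13 on the log2 scale.

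**Figure D1:**
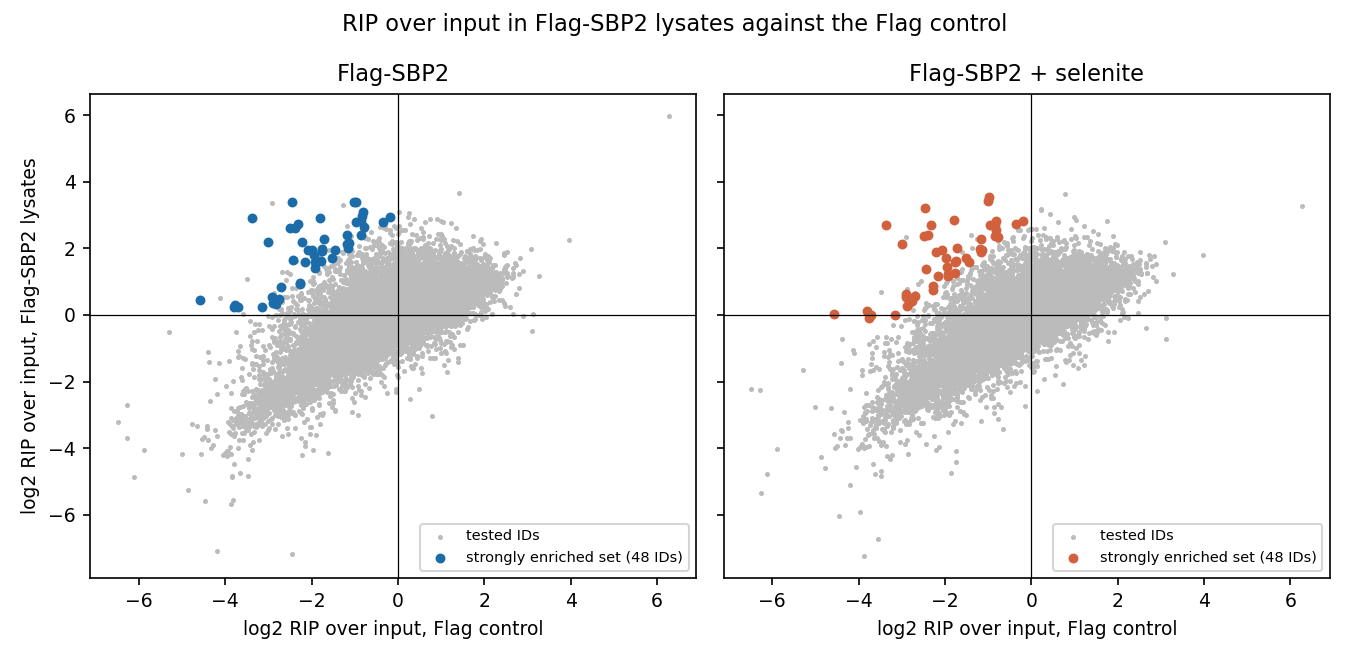
Each point is 1 of 17678 tested IDs, with the log2 RIP-to-input ratio of the Flag control on the x axis and that of Flag-SBP2 (left) or Flag-SBP2 with selenite (right) on the y axis, and the strongly enriched set in colour. The 48 IDs of the set lie between -4.58 and -0.18 in the control, between 0.23 and 3.40 with SBP2 and between -0.079 and 3.54 with SBP2 and selenite, and the slope across IDs is 0.591 without and 0.634 with selenite.

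With selenite, ENSG00000198832 and ENSG00000167468 were the first 2 IDs by enrichment over control, at log2 6.06 (SE 0.143, 66.9-fold, edgeR adjusted p = 4.78e-20) and 5.66 (SE 0.139, 50.6-fold, edgeR adjusted p = 5.9e-20). Their RIP-to-input ratios were 2.69 ± 0.065 and 3.20 ± 0.027 (SD, n = 3). ENSG00000271971 fell by 1.76 (SE 0.32, edgeR adjusted p = 0.000114), and RIP against RIP without inputs gave -1.13 (edgeR adjusted p = 1.41e-05). ENSG00000165029 fell by 1.65 (SE 0.451, edgeR adjusted p = 0.00579), from 2.37 ± 0.65 in control to 0.61 ± 0.52 with SBP2 and selenite. That ID lay at 0.633 ± 0.452 CPM in control input, and the comparison without inputs gave -0.40 (edgeR adjusted p = 0.195). In total there were 3416 enriched and 2540 depleted IDs, with 1367 and 294 at 2-fold or more. The share enriched was 57.4%, against 45.0% with DESeq2 size factors (2784 enriched, 3397 depleted) and 42.7% with library size alone (2670 and 3582).

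Enrichment with and without selenite covered largely overlapping IDs. Of those enriched, 3156 were shared, against 742.8 for independent lists of these sizes. Of those depleted, 2274 were shared, against 459.9 for independent lists. Simulations shared means of 0 and 0.05, but they held no effects, so these values do not measure what the common controls add to lists of this size. No ID changed in opposite directions (0 of 17678). Across IDs, which are not independent replicates, the enrichments correlated at r = 0.896, against 0.508 in the simulations. Their covariance was 0.528 against 0.0647, a difference of 0.464. The simulations held the noise of the shared controls, so the covariance difference is what remained beyond it as modelled. Both comparisons used the same 3 control lysates, which were too few to split. Part of the overlap beyond independent lists may therefore come from the shared controls.

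Among IDs with a mean log2 CPM of 1 or more, the strong end of the enrichment lay in 1 direction. At a log2 limit of 1, 1076 of these IDs were enriched and 176 depleted both with and without selenite. At limits of 2, 3, 4 and 5, 220, 48, 12 and 4 of them were enriched and 0 depleted. Less abundant IDs were not counted here. The 48 IDs at a limit of 3 formed the strongly enriched set, a limit chosen after these counts were seen. Their mean log2 RIP-to-input ratio was -1.99 ± 0.11 in control, 1.86 ± 0.064 in SBP2 and 1.68 ± 0.072 in SBP2 lysates with selenite (SD, n = 3).

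**Figure D2:**
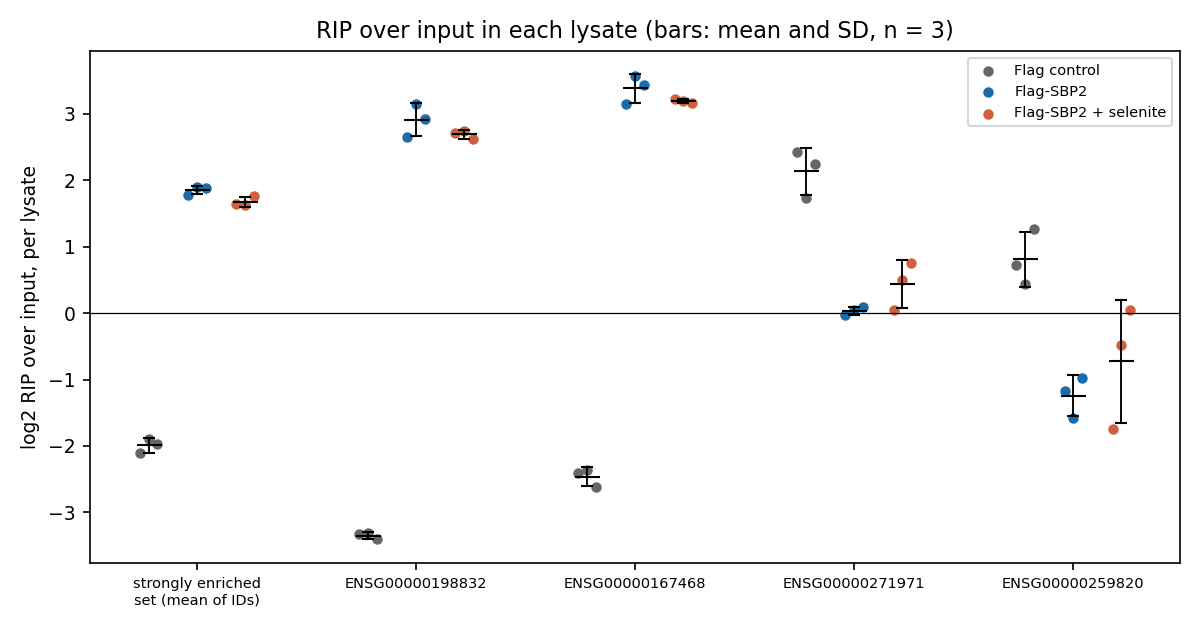
Points give the log2 RIP-to-input ratio of each lysate for the mean of the 48 IDs of the strongly enriched set and for 4 named IDs, and bars give mean and SD (n = 3). The set mean lies between -2.11 and -1.90 in control lysates and between 1.63 and 1.90 in all SBP2 lysates.

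Whether selenite changed recovery with SBP2 was tested as the difference between both SBP2 treatments. No ID passed: edgeR called 0 higher and 0 lower, with a smallest adjusted p of 0.989. An unadjusted edgeR p under 0.05 was reached by 800 IDs, fewer than evenly spread p-values would give. DESeq2 and limma voom also called 0. ENSG00000198832 differed by -0.22 (SE 0.127) and ENSG00000167468 by -0.19 (SE 0.129), both at an edgeR adjusted p of 0.989. Over the 48 IDs of the strongly enriched set, the mean ratio was 0.18 lower with selenite (difference -0.18, two-sided exact permutation p = 0.1, the smallest that 3 against 3 lysates allow), and 42 of 48 IDs were lower. The mean was lower in 3 of 3 same-numbered pairs of lysates (two-sided exact paired permutation p = 0.25, the smallest that 3 pairs allow). Camera with the preset correlation gave an adjusted p of 1.95e-11, but adjusted p = 0.0704 with an estimated correlation, and fry gave adjusted p = 0.104 for 1 direction and a mixed adjusted p of 0.0461 for change in either direction. With the lysate as a block the last 3 were 0.0523, 0.0763 and 0.0112, and 1 ID of the set passed when adjusted over the set alone, against 0 without the block.

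SBP2 inputs against control inputs gave the effect of Flag-SBP2 on RNA levels in the lysate. The transfected gene could not be looked up by name. ENSG00000187742 rose from 55.1 ± 3.1 to 2830 ± 259 CPM (SD, n = 3; log2 5.69, SE 0.148, 51.5-fold, edgeR adjusted p = 7.73e-12). ENSG00000130513 rose from 1.33 ± 0.18 to 12.3 ± 1.15 CPM (log2 3.20, SE 0.17, edgeR adjusted p = 1.03e-07). ENSG00000143224 fell from 32.1 ± 5.28 to 13.8 ± 2.63 CPM (log2 -1.20, SE 0.169, edgeR adjusted p = 0.00491). ENSG00000196668 fell from 4.48 ± 0.445 to 2.07 ± 0.264 CPM (log2 -1.09, SE 0.205, edgeR adjusted p = 0.0251), and it no longer passed without any 1 of 5 input libraries (adjusted p from 0.0572 to 0.144). In all 60 IDs were higher and 86 lower, 41.1% higher, against 52.9% with upper-quartile scaling (64 higher, 57 lower). Other settings moved the counts further, to 130 and 201 with DESeq2, 431 and 549 with limma voom, 370 and 311 without a low-count filter and 229 and 473 in a fit over 18 libraries. The replicate number as a block moved them most, to 1233 and 1501, with same-number correlations of 0.089 to 0.28 between these inputs. The main counts depended on single libraries. They rose to 398 and 339 without control replicate 1, and fell to 20 and 27 without control replicate 2 and to 31 and 17 without control replicate 3. Without SBP2 replicates 1, 2 and 3 they were 19 and 6, 17 and 4, and 23 and 27.

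SBP2 inputs with against without selenite gave the effect of selenite on RNA levels. ENSG00000178980 rose from 64.9 ± 12.6 to 147 ± 9.65 CPM (SD, n = 3; log2 1.18, SE 0.125, edgeR adjusted p = 0.00216). It was the only ID of 16616 to pass. An unadjusted edgeR p under 0.05 was reached by 251 IDs, fewer than evenly spread p-values would give. That count is no sign of further changes, and the test without a block may miss some. DESeq2 called 3 higher and limma voom 2, and 0 were lower with any of these tools. With the replicate number as a block, edgeR called 5 higher and 32 lower. Without the block and without a low-count filter it called 5 and 22. ENSG00000178980 was also enriched with SBP2 over control, at log2 5.03 without and 5.01 with selenite, and belonged to the strongly enriched set. Of that set 13 IDs were higher and 35 lower with selenite, and the median was -0.064. Adjusted over the list alone, 4 passed, all of them higher, and 14 with the block, of which 5 were higher. Among these 4, ENSG00000233276, chosen after its values were seen, was higher by 0.61 (SE 0.097, p adjusted over the set 0.000453, edgeR adjusted p over all IDs 0.157). Since the set was chosen on these libraries, this count is not independent evidence. Camera gave adjusted p = 0.261 (0.615 with an estimated correlation), and fry gave adjusted p = 0.849 for 1 direction and a mixed adjusted p of 0.00186 for change in either direction.

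SBP2 inputs with selenite against control inputs gave both changes together. ENSG00000187742 rose to 3050 ± 583 CPM (log2 5.79, SE 0.149, edgeR adjusted p = 6.36e-12) and ENSG00000130513 to 12.8 ± 0.875 CPM (log2 3.25, SE 0.17, edgeR adjusted p = 8.03e-08). ENSG00000167700 fell from 109 ± 11.4 to 53.8 ± 12.2 CPM (log2 -1.02, SE 0.157, edgeR adjusted p = 0.00896), and did not pass without selenite replicate 1 (adjusted p = 0.0511) or 2 (0.0688). ENSG00000100889 fell from 106 ± 37.0 to 52.5 ± 11.3 CPM (log2 -1.01, SE 0.198, edgeR adjusted p = 0.0353), and did not pass without control replicate 3 or without any 1 selenite replicate (adjusted p from 0.0563 to 0.26). Nor did it pass with the stricter low-count filter (adjusted p = 0.0555) or a fit over the compared groups (0.103). In all 51 IDs were higher and 41 lower, and 375 and 755 with the replicate number as a block. DESeq2 gave 94 and 112, limma voom 174 and 292, no low-count filter 162 and 167, a fit over 18 libraries 144 and 215, and a fit over the compared groups 21 and 11. The share higher was 55.4%, against 67.8% with upper-quartile scaling (59 and 28) and 68.6% with library size alone (59 and 27). Without selenite replicates 1, 2 and 3 the counts were 21 and 8, 22 and 1, and 48 and 86. Without control replicates 1, 2 and 3 they were 59 and 69, 28 and 26, and 35 and 10. Of the IDs higher than control inputs, 40 were shared with SBP2 inputs without selenite (0.184 for independent lists), and of those lower 38 were shared (0.212). Simulations shared 0, but they held no effects and no structure by replicate number. Part of this excess may come from the shared control inputs.

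**Figure D3:**
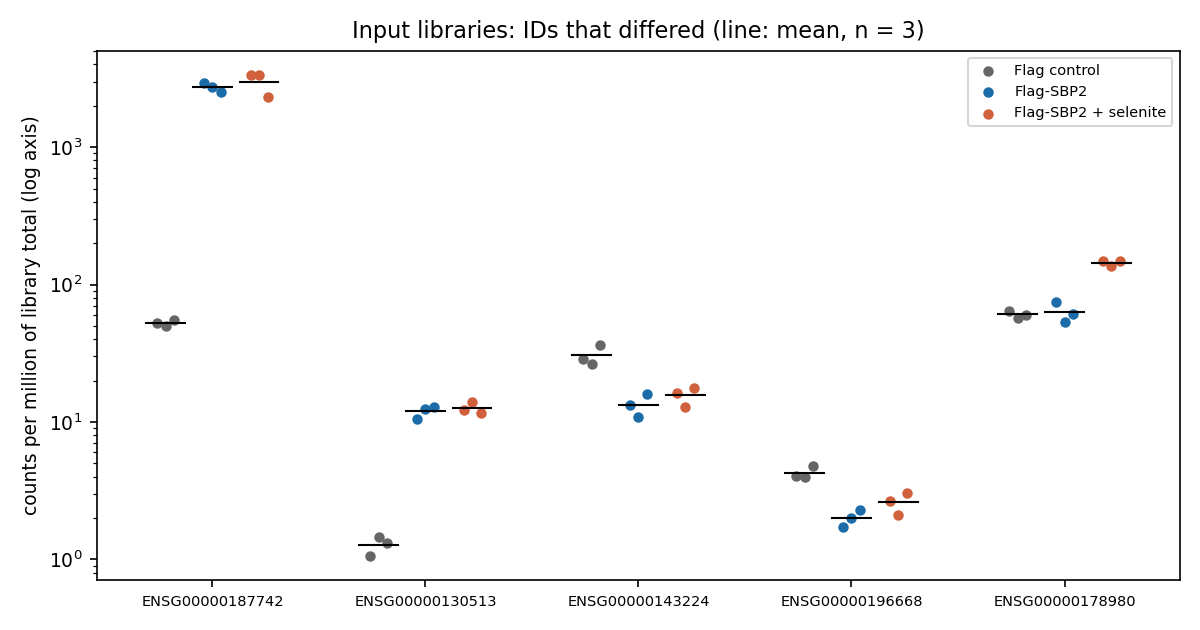
Points give CPM relative to the library total in each input library, on a log axis, for 5 IDs that differed between inputs, and lines give the mean (n = 3). ENSG00000187742 and ENSG00000130513 lie higher in all SBP2 inputs than in control inputs, and ENSG00000178980 lies higher in the selenite inputs than in the other 6.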

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

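The sample splits and the scalings were set before the data were examined. The use of the scalings to weigh an explanation, and the tests of compression and depth, were chosen after the enrichments were seen. Many IDs moved to opposite sides of the input in control and SBP2 RIP, with a difference that passed edgeR's test. Without selenite, 788 IDs were below input in control RIP and above it in SBP2 RIP, and 122 went the other way. With selenite these counts were 614 and 47.

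The broad difference between Flag-SBP2 and control RIP was weighed against technical explanations. More input-like RNA in SBP2 RIP can only bring ratios back toward 0, yet 1763 of the 3844 enriched IDs also passed above input, and at least 1555 under each other scaling, where the threshold allows at most 282 expected false calls above input. For the enriched IDs that did not pass above input compression stays open and untested: 75.8% of them had an SBP2 ratio between that of the control and 0, but this choice of IDs already favours such ratios. Over all tested IDs, 7045 differed in the SBP2 enrichment and 6721 after all libraries were thinned to 15.2 M counts, which argues against unequal depth as the whole cause. Under each other scaling at least 7068 differed. These scalings kept the median of all IDs between -0.13 and 0.022 on the log2 scale, so they tested small scaling errors alone. Larger scaling errors were not tested. Binding of RNAs by Flag-SBP2 or a partner may account for part of the pattern, as a hypothesis that no value here tests directly. Of the depleted IDs, 64.6% without and 77% with selenite had an SBP2 ratio between 0 and that of the control. For these, compression also stays open and cannot be told apart from a real loss or from other causes of a lower share of the library. The other depleted IDs lay outside that range, where input-like RNA alone would not bring them. Among them, 122 without and 47 with selenite passed above input in control RIP and below it in SBP2 RIP. Whether these exceed false calls was not tested.

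Of the 84 splits of the 9 lysates into 6 and 3, only the real one (1 of 84) gave as many IDs as SBP2 with and without selenite against control. It gave 7591, and the highest other gave 2. Every other split mixed control and SBP2 lysates in a group, which widens the spread within groups and keeps its count low. A share of 1 in 84 is also the smallest these splits allow. Chance in the grouping is thus unlikely for this pooled comparison, but not excluded. Single comparisons had 10 splits, too few for a share under 0.05. Real and highest other counts were 12610 and 0 for control RIP against input, 10968 and 0 for SBP2, 11003 and 0 for SBP2 with selenite, 7045 and 0 for SBP2 enrichment, and 5956 and 0 for enrichment with selenite. For selenite against SBP2 inputs they were 1 and 0. In each of these 6 comparisons only 1 split, the real one, reached the real count. For the selenite effect on enrichment all 10 splits gave 0.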

How the results depend on the processing

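Leaving out the ID most raised in SBP2 inputs, thinning libraries to 1 total, pairing lysates by number across SBP2 treatments and all alternatives for the strongly enriched set were chosen after seeing the data; the others were set before the data were examined. The named IDs kept their direction in 612 checks, with 598 past the threshold, 14 no longer past it and 0 reversed. These IDs were chosen on the same data, and the check with a fold limit reused the main fit for IDs already past that limit. The 598 are therefore not independent support. Where counts moved, the cause was not tested, except that a fold limit passes fewer IDs by construction. Counts are given as higher and lower IDs. A log2 limit of 1 gave 2299 and 3911 for control RIP against input, 1519 and 2605 for SBP2, 1491 and 2618 for SBP2 with selenite, 1691 and 592 for SBP2 enrichment and 1367 and 294 with selenite. It gave 32 and 5 for SBP2 against control inputs and 26 and 3 with selenite. RIP against RIP without inputs gave 4225 lower IDs for enrichment with selenite and 1 higher for the selenite effect, where no low-count filter gave 1 lower.

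For SBP2 against control inputs, counts were 370 and 311 without a low-count filter, 130 and 201 with DESeq2, 431 and 549 with limma voom, and 229 and 473 fitted over all 18 libraries. The lower count was 57 with upper-quartile factors and 55 with at least 50 counts in 3 libraries. For selenite against control inputs, counts were 162 and 167 without a filter, 94 and 112 with DESeq2, 174 and 292 with limma voom, 144 and 215 over all 18 libraries and 21 and 11 over the compared groups. The lower count was 27 with library size alone and 26 with the stricter filter. For selenite against SBP2 inputs, counts were 5 and 22 without a filter, and the higher count was 3 with DESeq2, 2 with limma voom, 3 over all 18 libraries and 2 over the compared groups.

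With the replicate number as a block, selenite against SBP2 inputs gave 5 and 32, and selenite against control inputs 375 and 755. For SBP2 against control inputs the block gave 1233 and 1501. Their same-number correlations were 0.089 to 0.28, the lowest under 0.1, against at most 0.043 with other numbers. All 9 inputs correlated best with their own number, a hint from the data and not the design. The lysate as a block moved no count of a RIP comparison by more than 1.5 times.

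With 1 library or lysate left out, ranges were 5292 to 5539 and 6537 to 6851 for control RIP against input, 5030 to 5103 and 5026 to 5277 for SBP2, and 5094 to 5243 and 5054 to 5320 with selenite. They were 3242 to 3812 and 2508 to 3325 for SBP2 enrichment, 2832 to 3422 and 2018 to 2639 with selenite, and 0 to 0 in both directions for the selenite effect. Inputs gave 17 to 398 and 4 to 339 for SBP2 against control (lowest without SBP2 replicate 2, highest without control replicate 1), 21 to 59 and 1 to 86 for selenite against control, and 1 to 1 and 0 to 0 for selenite against SBP2. The strongly enriched set held 34 to 49 IDs over its alternatives. Leaving out SECISBP2 or mitochondrial genes, the gene list tests and the SECIS motif test were not run, since IDs had no symbols and no genome sequence was used.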

Other observations

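The sample splits, the replicate block and the tests of single IDs between inputs were set before the data were examined, and the other tests in this part were chosen after the results were seen. Across IDs, the log2 RIP-to-input ratios of SBP2 lysates followed those of the control at r = 0.713 without and 0.767 with selenite, and those of both SBP2 treatments correlated at 0.927. ENSG00000143224 was lower in SBP2 than in control inputs, and its log2 RIP-to-input ratio was -1.01 ± 0.13 in control and 1.09 ± 0.19 in SBP2 lysates (SD, n = 3). The input is the denominator of this ratio, so its fall from 32.1 to 13.8 CPM makes up part of the change. In RIP the ID lay at 15.8 ± 1.18 CPM in control and 29.3 ± 2.67 CPM with SBP2.

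ENSG00000187742 had the largest rise of the named IDs in SBP2 inputs, and a candidate explanation is that it is the transfected gene, which no table used here can show. Leaving it out of library sizes and tests, an alternative added after seeing the data, left 45 IDs in the strongly enriched set, against 48.

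The mean ratio of the strongly enriched IDs was 0.18 lower in RIP with selenite, but whether this is a change stays open. The exact p was 0.1, the smallest that 3 against 3 lysates allow, so that test decides nothing at 0.05. No ID of 48 passed over all IDs, and with the lysate as a block 1 passed over the set alone. Set tests lay on both sides of 0.05, with adjusted p = 0.0704 for camera with an estimated correlation, 0.104 for fry in 1 direction and 0.0461 for fry in either direction (0.0523, 0.0763 and 0.0112 with the block). This shift of the set mean was -0.17 after thinning to equal totals and -0.16 at its weakest over the scalings. These values argue against unequal depth and the choice among these scalings as its whole cause. More background RNA in the selenite RIP libraries stays open and may contribute: the slope against the control profile was 0.636 ± 0.033 with and 0.592 ± 0.031 without selenite, a difference of 0.044 (two-sided exact permutation p = 0.2; the smallest possible is 0.1). The slope was higher with selenite in 3 of 3 same-numbered pairs (exact paired permutation p = 0.25, the smallest that 3 pairs allow). An effect of selenite on recovery also stays open.

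Replicate number marked a structure among inputs. All 9 of 9 inputs correlated best with an input of their own number, so inputs of 1 number may share a preparation, which the labels do not state. In SBP2 against control inputs 2 of 10 splits, the real one included, reached the real count of 146, and the higher, 334, set control replicate 1 with SBP2 replicates 1 and 2 against the rest. In selenite against control inputs 2 of 10, the real one included, reached 92, and the higher, 492, set control replicate 1 with selenite replicates 1 and 2 against the rest. Both splits kept the inputs of number 1 together and those of number 3 together, and parted those of number 2. A split into 3 and 3 must part at least 1 number, so both splits followed the number as far as such a split can. Their cause was not tested. With the number as a block, the former comparison gave 1233 higher and 1501 lower IDs, and the latter 375 and 755.

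A hypothesis that the strongly enriched IDs rise together in inputs with selenite was not borne out: their median log2 change was -0.064, although 4 single IDs passed over the list alone.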
